A study of Homo sapiens with 6 samples.

How the data were processed

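The 6 libraries came from MCF-7 cells treated with 10 nM 17β-estradiol for 0, 6 or 24 h, with 1 library for each time and each form of the reverse PCR primer. Per the labels, all libraries used the nested RT primer, and the protected ones differed in the phosphorothioate linkages of the reverse PCR primer. The labels do not say whether both primers were used on the same RNA or on separate cultures.

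The deposited files are lists of genomic coordinates, 1 per library: each line gives a chromosome, start, end and strand of a peak, with no score, read count or depth. Per the submitters' processing notes, the tools and build named are cutadapt, GSNAP and hg19, with no versions. The peak caller, its threshold and the handling of duplicate reads are not given in the sources used here. Every peak is 200 bases wide in the deposited lists, so a window marks a centre and not a footprint. Peaks of 1 list can overlap and were counted apart. The deposited lists of the 6 h unprotected and 24 h protected libraries end in an incomplete line on the minus strand of chromosome X, so these parts of chromosomes X and Y are incomplete there. An alternative left the minus strand of chromosome X and all of chromosome Y out of every list.

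From 507997 peaks, all values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, bedtools 2.31.1, samtools 1.23.1 and matplotlib 3.10.9. Sequences came from GRCh37, which is hg19 for the placed chromosomes, and genes from GENCODE release 44 placed on GRCh37. Mitochondrial peaks, and peaks with no sequence in that reference (no match by name, a window past the end, or unknown bases throughout), were left out of sequence steps, 836 peaks in all. Peaks were shared where they overlapped by at least 1 base on the same strand, with the other list shifted by 1000 bases as background.

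Primer sites were counted on the RNA-sense strand in each window: TCAGTC, which pairs with the 3′ end of the RT primer, and GTGTCA, which pairs with the end of the PCR primer. The background was every other 6-mer of the same base composition. All 4096 6-mers were compared between peaks found only without and only with protection, with 0.5 windows added to each count. Peaks were annotated by their centre on the same strand, in the order 3′ UTR, coding sequence, 5′ UTR, noncoding exon, intron and elsewhere. Seed matches to bases 2 to 8 were counted for 24 microRNA families taken as expressed in MCF-7 cells and 15 taken as not expressed, against windows shifted by 500 bases in both directions.

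Peaks per gene were counted over exons and introns on the same strand, and 2.61% of peaks counted for more than 1 gene. Ratios behind list medians and the choice of named genes used log2 of peaks per 10000 with 1 added, and ratios of peak shares printed for single genes and summed lists, exonic ones included, had nothing added. Each of 10 lists, with 196 different genes, was described by its median and its percentile among 10000 random lists drawn from the 200 genes nearest to each member in mean peak number (seed 1). The lists were estrogen-induced, estrogen-repressed, cell cycle, microRNA pathway, known microRNA targets, luminal breast, ribosomal protein, abundant messenger RNA, nuclear long noncoding RNA and markers of other cell types. XBP1 was in the estrogen-induced and luminal lists and CDC25A in the cell cycle and target lists. Ratios of peak shares for single genes have exact 95% binomial intervals.

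Unprotected and protected libraries were compared as 3 pairs by time with an exact two-sided sign-flip permutation of the mean difference, whose smallest p is 0.25, so no comparison could pass a threshold of 0.05. Estradiol times had 1 library each per primer, so no p is given for them. Shares of peaks have 95% Wilson intervals. Larger lists give narrower intervals, and none of the intervals covers differences between cultures or library preparations.

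The genes named are members of the 10 lists and, for each contrast, the 10 genes with the largest mean log2 ratio in each direction among genes with the same sign in every pair and at least 5 peaks in each library of the higher side, and the 10 genes with most peaks. The sites in ANKMY2, LRRC28, INVS, ZNF621 and KIAA0040 fall outside that rule. Genes on the minus strand of chromosome X are not named.

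The steps were tested on simulated data. TCAGTC implanted in 5% and 20% of 20000 windows was recovered at 5.05% and 20.0% and ranked 1 of 4096. All 6000 implanted partners of peaks were found, and the overlap step gave 5204 shared peaks at 0 h, as bedtools did. Of 200 simulated lists of 39 genes, 0.5% reached the 97.5th percentile with no implanted change, 99.5% with a 1.5-fold change and 100% with a 2-fold change. The simulated counts varied by Poisson counting error alone, and all 39 members had the same change. These rates therefore do not cover differences between library preparations and are no error rates for the real lists.

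Alternatives changed the overlap rule, site length, strand, window, control shift, pseudocount, minimum peaks and exon restriction, and left out each time pair. Alternatives that rank peaks by score, set beforehand, were not run, because the lists hold no score. Thinning every list at random to the shortest, leaving out peaks with TCAGTC for annotation and seeds, leaving out parts of chromosomes X and Y, and summed shares without the member, or for nuclear long noncoding RNAs also the 2 members, with most peaks were chosen after seeing the data.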

Results

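Argonaute binding sites were mapped in MCF-7 cells, an established estrogen receptor-positive human breast cancer line, by HITS-CLIP. In this assay, RNA crosslinked to Argonaute, the protein that carries microRNAs to their targets, is recovered by immunoprecipitation, reverse transcribed and sequenced. Cells kept in estrogen-free medium received 10 nM 17β-estradiol for 0, 6 or 24 h. All 6 libraries were made with a nested reverse transcription (RT) primer. They differed in the reverse PCR primer, which reached 3 bases further into the adapter than the RT primer and was either unmodified or had phosphorothioate linkages at its last bases, which block digestion by the exonuclease of the polymerase. Libraries made with these primers are called unprotected and protected here. The title of the series names mispriming artifacts, so the first question was whether peaks of the unprotected libraries lie at sites that match the primer, and the other was how Argonaute peaks differ over estradiol time.

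Each of the 3 times had 1 library per primer, with no replicates. The unprotected lists held 44222, 109007 and 138769 peaks at 0, 6 and 24 h, and the protected lists held 48625, 83049 and 84325. Every peak was a stranded window of 200 bases without a score, and sequencing depth could not be read from the lists. The ratio of unprotected to protected peak numbers was 0.909 at 0 h, 1.31 at 6 h and 1.65 at 24 h. The covered length was 8.67, 21.0 and 26.7 Mb without protection and 9.41, 15.8 and 15.8 Mb with it. Intervals below cover counting error only, and overlapping windows of a list are not independent.

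The 6-base RNA sequence that pairs with the 3′ end of the RT primer, TCAGTC, was found in 28.5% of unprotected peaks at 0 h (95% Wilson interval 28.1 to 29.0), 20.6% at 6 h (20.4 to 20.8) and 19.4% at 24 h (19.2 to 19.6). Protected peaks held it in 5.49%, 5.81% and 5.11%. The background, the mean share of the 179 other 6-mers of the same base composition, was 3.65% to 3.85% in every list. The SD over these 6-mers was 2.36 to 2.80 points. Protected shares lay within 1 such SD of the background, so this measure does not set them apart from other 6-mers. TCAGTC stood at 7.41, 5.51 and 5.19 times background without protection and at 1.5, 1.59 and 1.39 times background with protection. Over the 3 times the mean was 22.8% ± 4.96 (SD, n = 3) against 5.47% ± 0.350, higher without protection in 3 of 3 pairs. The difference of 17.4 points ± 4.91 was larger than the spread between times, but an exact two-sided sign-flip permutation over 3 pairs gave p = 0.25, the smallest it can give (Benjamini-Hochberg 0.286 over 8 tests). In annotated exons alone the difference was 10.6 points. The sequence that pairs with the end of the longer PCR primer, GTGTCA, was found in 4.85% ± 0.142 of unprotected and 4.87% ± 0.0490 of protected peaks (SD, n = 3; exact two-sided p = 0.75).

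Unprotected peaks held TCAGTC mostly downstream of their centre. Its starts were spread over a broad stretch and were most frequent 18 bases downstream at each time, where there were 11.9, 7.96 and 6.90 per 1000 peaks, 46.1, 32.1 and 28.1 times the background per base. Over the 60 bases downstream of the centre there were 237, 164 and 149 sites per 1000 unprotected peaks at 0, 6 and 24 h, against 20.1, 24.6 and 18.6 per 1000 protected peaks. Over the 60 bases upstream, unprotected peaks had 21.5, 18.8 and 16.8 sites per 1000 and protected peaks had 17.9, 17.3 and 17.4. Longer matches to the primer were more enriched downstream of unprotected peaks. A match of at least 6 bases was 15.8, 11.6 and 10.4 times as frequent as in background windows, and a match of at least 10 bases was 90.7, 43.1 and 55.1 times as frequent. With protection the 6-base matches were at 1.51, 1.75 and 1.33 times background and the 10-base matches at 9.0, 7.14 and 6.25 times. The 10-base values are imprecise, since their background windows held only 3, 10 and 9 sites without and 2, 7 and 4 with protection.

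**Figure D1:**
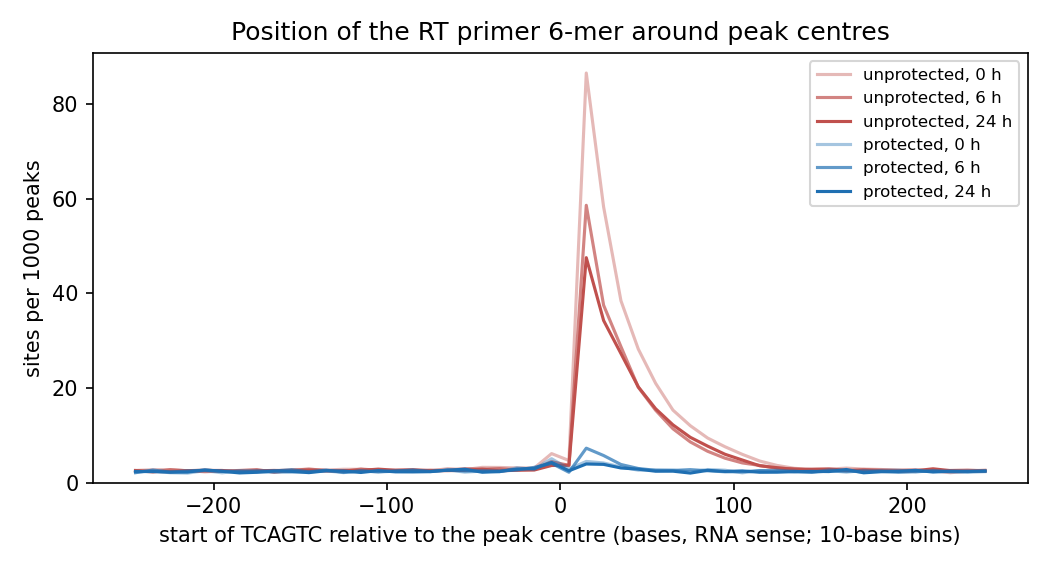
Starts of TCAGTC per 1000 peaks (vertical axis) in bins of 10 bases by distance from the peak centre in bases (horizontal axis), 1 line per library. The unprotected libraries peak downstream of the centre, with 86.6 sites per 1000 peaks in the bin that starts at 10 bases at 0 h. The protected libraries stay far lower, with at most 7.27 per 1000 in that bin, at 6 h, where the outermost upstream bin holds 2.09.

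Individual transcripts held long stretches of the primer sequence beside such peaks. Of the unprotected 24 h peaks, 6066 had a partner in all 3 unprotected lists and in no protected list, and 2246 of these (37.03%) held a match of 6 or more bases within 60 bases downstream of the centre. Among all 24 h peaks, TCAGTC lay in the 60 bases downstream in 13.7% without and 1.70% with protection. Most of the 6066 peaks thus held no such match. In 260 of them the match was 9 bases or longer, and in 32 it was 11 or longer. The longest matches, chosen after their values were seen, lay in introns of ANKMY2, LRRC28 and INVS and in the 3′ UTRs of ZNF621 and KIAA0040. In ANKMY2 the peak at chr7:16660739–16660938 (minus strand, hg19) held TCAGTCACTTCCAGC, 15 bases of primer complement at 16660795–16660809, starting 29 bases from the centre. The 3′ UTR of ZNF621 held TCAGTCACTTCCA, 13 bases, at chr3:40576743–40576755 (plus strand), 42 bases from the centre of the peak at 40576601–40576800. The 3′ UTR of KIAA0040 held the same 13 bases at chr1:175127390–175127402 (minus strand), 37 bases from the centre of the peak at 175127340–175127539. Introns of LRRC28, at chr15:99801084–99801096, and INVS, at chr9:102918931–102918943 (both plus strand), also held these 13 bases, 31 and 38 bases from the centres.

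Among all 6-mers, TCAGTC had the largest ratio between peaks found only without protection and peaks found only with it, with a mean log2 ratio of 2.47 ± 0.24 (SD, n = 3), or 5.54-fold. The next were shifted by 1 base or more from it: CAGTCA at 1.64, GTCAGT at 1.12, AGTCAC at 1.11 and ATCAGT at 1.10. The lowest ratio was that of CGACCG, at -0.94. TACCTC, the site for bases 2 to 7 of the let-7 microRNA, had the 16th lowest, at -0.73. GTGTCA ranked 1611, at -0.01.

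Few peaks were found with both primers. At 0, 6 and 24 h, 11.8%, 16.1% and 14.5% of unprotected peaks overlapped a protected peak by at least 1 base on the same strand, as did 11.6%, 22.0% and 24.9% of protected peaks. Shifting the other list by 1000 bases left 5.37%, 8.71% and 8.09% of unprotected and 5.20%, 11.7% and 13.8% of protected peaks with a partner, so sharing was 1.79 to 2.23 times this background. TCAGTC was in 29.7%, 21.8% and 20.5% of peaks found only without protection and in 19.3%, 14.5% and 12.7% of unprotected peaks found with both primers. Among protected peaks it was in 4.46%, 4.51% and 3.89% of those found only with protection and in 13.5%, 10.4% and 8.82% of those found with both. The shared percentage was 5.37 points ± 5.29 (SD, n = 3) higher in the protected lists, about the size of the spread between times, and higher in 2 of 3 pairs (exact two-sided p = 0.50). That difference depended on list length and on the pairs used: it was 0.78 points with every list thinned to 1 length, 8.13 without the 0 h pair and 2.86 without the 24 h pair.

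Protected peaks lay more often in mature messenger RNA, and unprotected peaks in introns. The 3′ UTR share was 11.7% ± 1.04 (SD, n = 3) without protection and 22.6% ± 2.83 with it, the coding share 7.84% ± 0.256 against 15.02% ± 1.70, and the intronic share 62.4% ± 1.39 against 43.7% ± 3.44. By time, the 3′ UTR share was 10.7%, 12.8% and 11.7% without protection and 20.2%, 21.9% and 25.7% with it. The 5′ UTR held 0.834% and 1.22% of peaks, noncoding exons 2.84% and 3.35%, and positions outside genes on the same strand 14.3% and 14.2%. The differences in 3′ UTR share, -10.8 points ± 2.70, and in intronic share, 18.7 points ± 4.34, had the same sign in 3 of 3 pairs and were larger than the spread between times. For both, the exact two-sided sign-flip permutation gave p = 0.25, the smallest possible with 3 pairs (Benjamini-Hochberg 0.300 over 6 tests).

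Peaks found with both primers had the largest 3′ UTR shares: 33.3%, 40.5% and 42.6% of such unprotected peaks and 36.2%, 43.8% and 46.1% of such protected peaks at 0, 6 and 24 h. Unprotected peaks with TCAGTC were in 3′ UTRs in 8.16%, 8.05% and 7.82% of cases and in introns in 73.9%, 74.9% and 75.3%. Unprotected peaks without it were in 3′ UTRs in 11.8%, 14.0% and 12.7%.

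**Figure D2:**
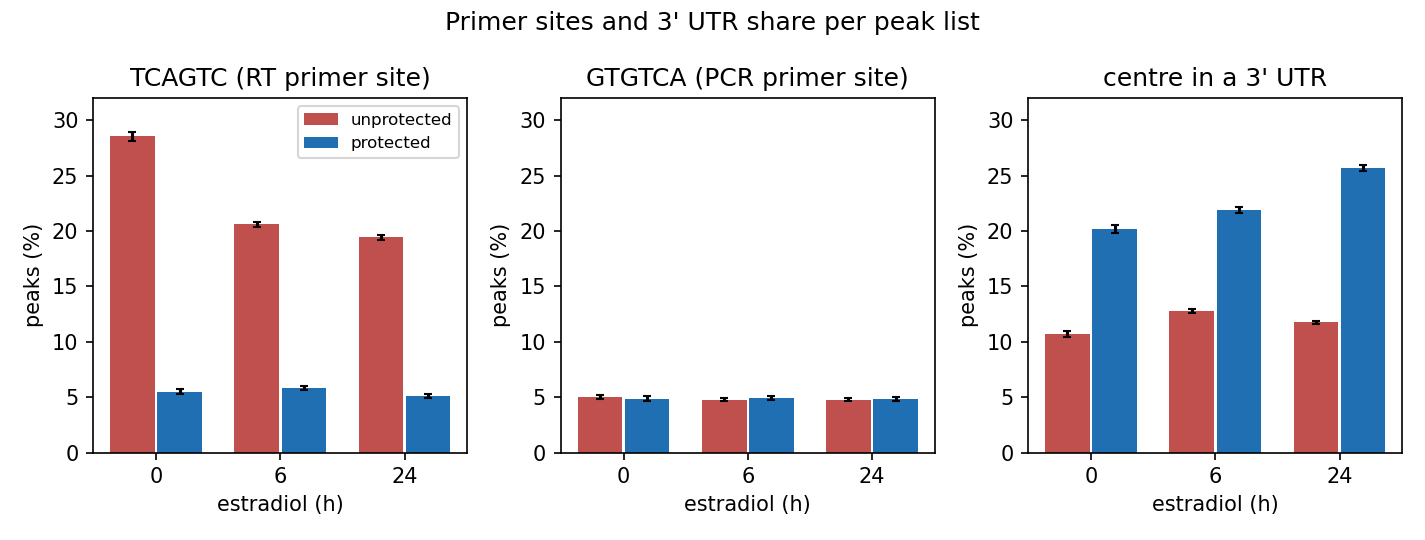
Percentage of peaks (vertical axes) that hold TCAGTC, that hold GTGTCA and that lie in 3′ UTRs, 1 panel each, for each estradiol time and primer, with 95% Wilson intervals that cover counting error only. TCAGTC is at 19.4% to 28.5% without protection and 5.11% to 5.81% with it, and the 3′ UTR share is at 10.7% to 12.8% and 20.2% to 25.7%.

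Seed matches of most microRNA families taken as expressed in MCF-7 cells were more enriched in protected than in unprotected peaks. A seed match is the site for microRNA bases 2 to 8, and its enrichment is its share of peaks over its share of windows shifted by 500 bases. The let-7 family, abundant in differentiated epithelial cells, stood highest with protection, at 2.76 ± 0.323 (SD over 3 times) against 1.35 ± 0.0667 without. Its site was in 3.39%, 3.0% and 3.8% of protected peaks and 1.60%, 1.63% and 1.49% of unprotected peaks at 0, 6 and 24 h. The miR-15/16 family was at 1.75 with protection and 1.21 without, miR-103/miR-107 at 1.65 and 1.17, miR-19 at 1.44 and 1.12, miR-27 at 1.43 and 1.10, and miR-25/92 at 1.25 and 0.784. Levels depended on the control windows. For 3′ UTR peaks against shifted windows also in 3′ UTRs, miR-25/92 was at 1.77, 1.60 and 1.69 with protection at 0, 6 and 24 h. Without protection it was at 0.931, 1.02 and 0.983 there.

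Of the 24 families taken as expressed, 21 had higher enrichment with protection at all 3 times. In 1, miR-203, it was lower at all 3, with 1.12 with and 1.24 without protection, and miR-191 had means of 1.28 and 1.33. Of 15 families taken as not expressed, 7 were higher at all 3 times and 3 were lower. With protection, enrichment ranged from 0.967 to 2.76 (median 1.27) in families taken as expressed. It ranged from 0.867 to 1.27 (median 1.12) in the others, so both ranges overlapped. Together, sites of the expressed families were at 1.25 ± 0.0409 with protection and 1.06 ± 0.0145 without, a log2 difference of 0.24 ± 0.07. Sites of the other families were at 1.07 and 1.04, a difference of 0.04. The let-7 difference was 1.03 ± 0.20. Each of these was positive in 3 of 3 pairs, and the exact two-sided permutation could not give p below 0.25 (Benjamini-Hochberg 0.301 over 41 tests). Their size depended on the site counted: sites for bases 2 to 7 gave 0.64 for let-7 and 0.07 for the expressed families, and sites with an adenine opposite base 1 gave 1.32 and 0.47.

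**Figure D3:**
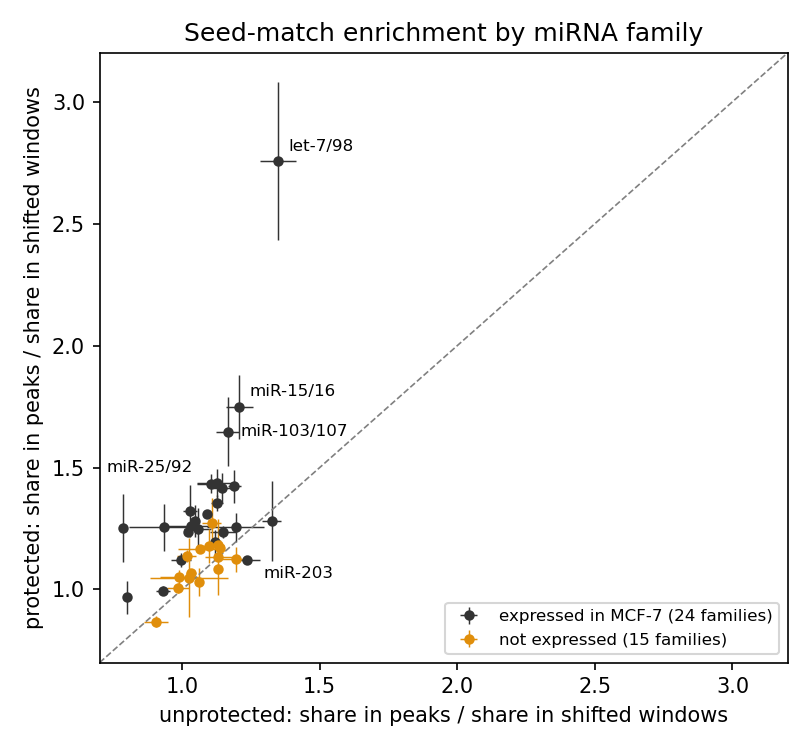
Enrichment of seed matches over shifted windows without protection (horizontal axis) and with protection (vertical axis), 1 point per microRNA family, as the mean over 3 times with the SD, for 24 families taken as expressed in MCF-7 cells and 15 taken as not expressed. Points above the dashed line of equality are higher with protection, with let-7 the highest at 2.76 against 1.35.

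Genes differed in how many peaks each primer gave. Counts of peaks per gene over its whole length were set against the length of the list, and the ratio of such shares has an exact 95% interval. ERBB4, which encodes a receptor tyrosine kinase (chr2:212240442–213403565), had 92, 199 and 250 unprotected peaks at 0, 6 and 24 h and 7, 12 and 2 protected peaks, a share 14.5 times (6.74 to 36.9), 12.6 times and 76.0 times as large. LRFN5, a synaptic adhesion molecule (chr14:42076079–42373752), had 95, 218 and 258 against 9, 15 and 8, or 11.6, 11.1 and 19.6 times. HMCN1, an extracellular matrix protein (chr1:185703523–186160081), had 49, 133 and 151 against 2, 2 and 1. SLIT2, an axon guidance ligand (chr4:20253528–20622184), had 39, 69 and 72 against 1, 1 and 3, and NECAB1 (chr8:91803969–91971621) had 11, 44 and 44 against 1, 0 and 0. Few of these peaks were exonic in ERBB4, with 2, 2 and 4 unprotected against 1, 2 and 0 protected, and in LRFN5, with 3, 8 and 9 against 2, 1 and 1. HMCN1 had 8, 15 and 22 exonic peaks without and 1, 1 and 0 with protection. As log2 ratios of exonic shares, ERBB4 was at 1.98 at 0 h and 0.30 at 6 h, and LRFN5 at 1.56, 3.30 and 3.49.

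Other genes had more protected peaks. SNTG1, a syntrophin (chr8:50822349–51709252), had 2 unprotected peaks at each time and 16, 17 and 30 protected peaks. STC2, a secreted glycoprotein hormone (chr5:172741726–172755450), had 1, 4 and 12 against 18, 30 and 14. SALL4 (chr20:50398870–50419060) and TFAP2A (chr6:10393419–10419892), both transcription factors, had 3, 4 and 1 against 19, 10 and 19, and 1, 4 and 5 against 12, 16 and 16. The ratio was above 1 at all 3 times, with at least 5 peaks in each unprotected library, in 867 genes, and below 1, with at least 5 in each protected library, in 763. Genes that met each floor were not counted, and a floor of 5 peaks is easier to reach in a longer list. These counts therefore do not compare the directions.

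Most gene lists set before the data were examined had lower medians without protection, though few did so under every setting. Each list is described by the median log2 ratio of peaks per 10000 and its percentile among 10000 random lists matched on peak number. Unprotected over protected, estrogen-induced genes were at -0.15, -0.23 and -0.27 at 0, 6 and 24 h (percentiles 2.18, 0.01 and 0) and genes of the microRNA pathway at -0.40, -0.21 and -0.35 (percentiles 0.41, 1.36 and 0.13). Abundant messenger RNAs were at -0.21, -0.24 and -0.33, estrogen-repressed genes at -0.27, -0.18 and -0.21, known microRNA targets at -0.05, -0.04 and -0.16, and cell cycle genes at -0.15, -0.0068 and -0.23. Luminal breast genes were at -0.33, -0.29 and 0.05, ribosomal protein genes at 0.02, -0.23 and -0.02, nuclear long noncoding RNAs at -0.11, -0.0050 and -0.26, and markers of other cell types at 0, 0 and 0.02. Percentiles stayed at or below 2.5 under every alternative run only for estrogen-induced genes at 6 h and the microRNA pathway at 24 h. With exonic peaks alone the percentiles of estrogen-induced genes were 38.2, 0.05 and 3.66, and several medians changed sign: nuclear long noncoding RNAs were at 0.66, 0.46 and 0.49, abundant messenger RNAs at 0.33, -0.06 and 0.16, luminal genes at 0.10, 0.12 and 0.34, cell cycle genes at 24 h at 0.01 and ribosomal protein genes at 24 h at 0.20.

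Estrogen-induced genes held a larger share of Argonaute peaks after estradiol with both primers. At 24 h, 31 of 39 measured members were higher without protection and 6 lower, with a median log2 ratio to 0 h of 0.36. With protection 30 were higher and 9 lower, with a median of 0.38. Both medians were at percentile 100 of random lists. At 6 h the medians were 0.16 (percentile 96.0) and 0.37 (percentile 100). Their summed share of peaks at 24 h was 1.65 times that at 0 h without protection (1.41 to 1.93) and 1.92 times with it (1.66 to 2.23), and 1.54 (1.28 to 1.87) and 1.51 (1.28 to 1.78) without GREB1. AREG had no peaks in any list. With 1 library per time, a percentile describes these libraries and is no test of the treatment.

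GREB1, an estrogen receptor target that promotes growth (chr2:11622467–11782914), had 26 protected peaks at 0 h and 234 at 24 h, a share 5.19 times as large (3.45 to 8.11). Without protection it had 55 and 327, or 1.89 times (1.42 to 2.57). On exonic peaks alone, 9 and 52 with protection, the log2 ratio of shares was 1.53. PGR, the progesterone receptor (chr11:100900355–101000544), had 2 and 19 protected peaks, 5.48 times (1.32 to 48.5), and 1 and 36 unprotected peaks, 11.5 times (1.93 to 466). EGR3, a transcription factor (chr8:22545172–22550993), had 3 and 20 protected peaks, 3.84 times (1.14 to 20.2), and 0 and 10 unprotected peaks. CXCL12, a chemokine (chr10:44865613–44881941), had 0, 18 and 20 protected peaks at 0, 6 and 24 h and 2, 3 and 11 unprotected peaks. NRIP1, a nuclear receptor corepressor (chr21:16333556–16438257), was at 4.78 times without protection (1.53 to 24.0) and 2.09 times with it (0.932 to 5.29), and CELSR2, a cadherin (chr1:109792161–109818373), at 3.13 times with protection (1.38 to 8.31).

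Intervals lay above 1 at 24 h in 3 members of the estrogen-induced list without protection, namely GREB1, PGR and NRIP1, and in 7 with it. With protection the interval of STC2 lay below 1, at 0.448 (0.206 to 0.954). For MYC (chr8:128747680–128755197) and TFF1 (chr21:43782391–43786644), well-known estrogen targets with few peaks, the interval included 1 with both primers: MYC had 6 and 16 protected peaks at 0 and 24 h and TFF1 had 2 and 8. Outside the lists, THSD4, a thrombospondin repeat protein (chr15:71389291–72075722), was among the genes with the largest ratios, 3.08 times (2.02 to 4.88) with protection and 3.05 times (2.01 to 4.80) without. On exonic peaks alone, 1 and 6 without protection at 0 and 24 h, its log2 ratio of shares was 0.92. With protection it had 0 and 11 exonic peaks at these times.

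The luminal and estrogen-repressed lists held smaller summed shares of protected peaks after estradiol. At 24 h, 15 luminal genes had a median of -0.40 with protection (percentile 0.05) and -0.01 without (percentile 29.2), with summed shares of 0.633 (0.550 to 0.727) and 0.797 (0.696 to 0.914) times those at 0 h. ESR1 held 205 of 392 protected and 144 of 298 unprotected luminal peaks at 0 h, and without it the shares were 0.666 (0.545 to 0.814) and 0.888 (0.737 to 1.07) times. On exonic peaks alone the protected percentile of the median was 5.16. ESR1, the estrogen receptor itself (chr6:151977826–152450754), had 205 and 214 protected peaks at 0 and 24 h, a share of 0.602 times (0.495 to 0.733), and 144 and 316 unprotected peaks, 0.699 times (0.572 to 0.858). On exonic peaks alone, 7 and 26 without protection, its log2 ratio of shares was positive, at 0.23. GATA3 (chr10:8087341–8117161) and FOXA1 (chr14:38058757–38065264), transcription factors of luminal cells, were at 0.472 (0.295 to 0.750) and 0.288 (0.0985 to 0.763) with protection. FOXA1 had 1 and 9 unprotected peaks. The 17 measured estrogen-repressed genes had medians at 24 h of -0.27 (percentile 0.125) with and 0.07 (percentile 57.6) without protection, and summed shares of 0.663 (0.486 to 0.906) and 0.797 (0.529 to 1.22). With thinned lists the protected percentile was 5.00. BMF, CYP1A1 and BIK had no peaks.

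Of the 28 cell cycle genes of S, G2 and M phase, 20 were higher at 24 h with protection and 8 lower, with a median of 0.30 (percentile 99.9) and a summed share of 1.47 times (1.13 to 1.91). No member had an interval above 1, and on exonic peaks alone the median was 0.20 (percentile 87.7). Without protection the median was -0.01 (percentile 16.5) and the share 1.08 times. Genes of the microRNA pathway had medians of 0.18 (percentile 89.5) without and 0.11 with protection, known microRNA targets of 0.00 with both primers, ribosomal protein genes of 0.07 and -0.09, and abundant messenger RNAs of -0.09 and -0.10. Of 15 marker genes of other cell types found in the annotation by name, 6 had any peak, with 0 to 6 peaks per list in all. PECAM1, also on that list, was not found by name and was not counted.

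The list of nuclear long noncoding RNAs held MALAT1, NEAT1, KCNQ1OT1, SNHG1, GAS5, TUG1, NORAD and MEG3. Where these RNAs lie in the cell was not measured, and nuclear is only the name of the list. Summed, the list held smaller shares at 24 h, 0.530 times (0.435 to 0.649) without and 0.733 times (0.607 to 0.885) with protection. These sums rest largely on MALAT1 and NEAT1, with 115 of 161 unprotected peaks at 0 h. Without NEAT1 they were 0.525 (0.400 to 0.692) and 0.824 (0.638 to 1.07) times, and without NEAT1 and MALAT1 0.797 (0.561 to 1.15) and 0.870 (0.612 to 1.25) times. The median of the 8 genes was -0.28 (percentile 0.67) without protection, where 7 were lower, and -0.18 (percentile 8.70) with it, where 5 were lower and 2 higher. MALAT1 (chr11:65265111–65275544) was at 0.228 (0.138 to 0.372) and 0.773 (0.528 to 1.14), and NEAT1 (chr11:65190245–65213011) at 0.537 (0.399 to 0.727) and 0.635 (0.479 to 0.844). Windows covered 48.0% to 65.9% of MALAT1 and 54.7% to 77.1% of NEAT1 in the 6 lists. At 24 h the lists were 3.14 times as long as at 0 h without and 1.73 times as long with protection. The covered length of both genes could not grow in step with that. This limit does not account for unprotected MALAT1, where windows fell from 42 to 30 and the covered length from 61.2% to 48.0%. Covered length also did not cap the number of windows: protected MALAT1 went from 50 to 67 windows at 65.9% and 65.3% covered. Long genes with smaller shares at 24 h with both primers included AUTS2 (chr7:69063282–70258492), at 0.376 with and 0.223 without protection, CTNND2, a catenin (chr5:10971948–11904558), at 0.288 and 0.364, NPAS3, a transcription factor (chr14:33403602–34290069), at 0.362 and 0.392, and SMAD3, a transducer of TGF-beta signals (chr15:67356101–67487511), at 0.376 and 0.431. Few of the protected peaks were exonic: AUTS2 had 1 and 2 at 0 and 24 h, a log2 ratio of shares of -0.0026, and SMAD3 had 3 and 5, or -0.27. BCAS1 (chr20:52553316–52687133) had 12 and 1 protected and 14 and 10 unprotected peaks at 0 and 24 h.

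**Figure D4:**
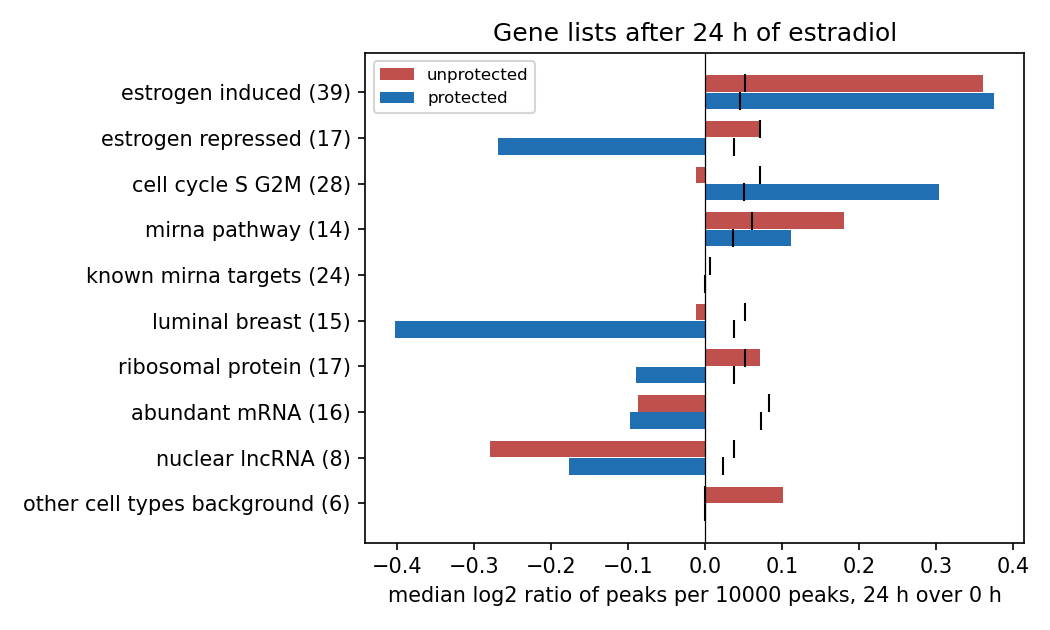
Median log2 ratio of peaks per 10000 at 24 h over 0 h (horizontal axis) for each gene list (vertical axis, measured members in brackets), with bars for each primer and black ticks for the median of random lists matched on peak number. Estrogen-induced genes are at 0.36 and 0.38, and luminal and estrogen-repressed genes are at -0.40 and -0.27 with protection.

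The ratios of single genes were weakly related between primers. Genes with at least 20 peaks summed over the 4 libraries compared were used. Over 3997 genes, the log2 ratios of 24 h to 0 h in the unprotected and protected libraries had a Pearson r of 0.19 and a Spearman rho of 0.16, and 57.5% of genes had the same sign. At 6 h, r was 0.18, rho 0.16 and the same-sign share 56.4% over 3540 genes. At such low counts, counting error alone lowers a correlation, so these values do not measure disagreement between primers. These correlations run across genes, which are not independent replicates.

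Unprotected peaks recurred more often over time than protected peaks. Of unprotected 0 h peaks, 38.6% had a partner at 6 h and 49.0% at 24 h, and of protected 0 h peaks 27.2% and 29.0%. List length bears on these shares: with every list thinned at random to the length of the shortest, 18.1% of unprotected and 18.5% of protected 0 h peaks had a partner at 24 h.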

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

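No explanation was tested for the values in this part, and none of the differences in it was tested. No test here was chosen after the result was seen.

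Estrogen-repressed genes and 10 of 39 microRNA families were above 0 h at both 6 and 24 h with 1 primer and below it at both times with the other. Lists and families whose own sign differed between 6 and 24 h were not counted. The estrogen-repressed list was the 1 of 10 gene lists with this pattern: its median log2 ratio of 24 h to 0 h was higher without protection by 0.34. Its unprotected median of 0.07 equalled that of random lists, and its summed share at 24 h was below that at 0 h with both primers, at 0.797 without and 0.663 with protection. For microRNA families, the value is the log2 seed enrichment at 24 h minus 0 h, unprotected minus protected. Among families taken as expressed in MCF-7 cells it was -0.17 for miR-182, 0.13 for miR-34/miR-449, -0.13 for miR-203 and -0.38 for miR-191. Among families taken as not expressed, which give a measure of background, it was 0.095 for miR-133, 0.44 for miR-208, 0.18 for miR-142-3p, -0.29 for miR-142-5p, -0.12 for miR-217 and 0.79 for miR-451. Families taken as not expressed make up 6 of the 10.

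Some classes of peaks were present in every list and were not compared between libraries as classes of their own. Mitochondrial RNA held 114 to 145 peaks per list, and unplaced sequences held 93 to 294. Peaks antisense to an annotated gene, with no gene on their own strand, were 5.06% to 6.42% of each list.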

How the results depend on the processing

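Alternatives added after seeing the data were thinning, leaving out peaks with TCAGTC, leaving out the minus strand of chromosome X with chromosome Y, and, for summed shares of lists, leaving out the members with most peaks; alternatives that rank by score were not run, since the lists hold no score. Changes were set against the SD over 3 pairs, the Wilson interval of a share or the bootstrap interval of a list's median, and the cause was not tested unless stated. Of 75 alternative values of results that answer a comparison, 50 stayed within that spread, 24 moved with the same sign and 1 changed sign. A change of sign was counted for values with a called direction: pairs of 1 sign, list medians among the lowest or highest 2.5% of random lists, and genes whose interval left out 1. For gene lists 436 stayed, 27 moved and 6 changed sign, for named genes 191, 10 and 1, and for other values 41 stayed and 20 moved.

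The share of unprotected 0 h peaks found at 24 h was 45.9% with 50% reciprocal overlap, 42.5% with centres within 50 bases and 18.1% thinned, and that of protected peaks 24.0%, 19.6% and 18.5%. The TCAGTC difference was 8.95 points with 7 bases of the site and 3.41 with 8, both rarer by construction, 10.6 in exons and -0.70 on the opposite strand, which serves as a control. The log2 ratio of TCAGTC was 2.04 over all peaks and 2.84 within 50 bases of the centre. Log2 seed differences with sites that add an adenine opposite base 1 (8mer), with bases 2 to 7 (6mer) and within 50 bases of the centre were 1.32, 0.64 and 1.37 for let-7, 0.47, 0.068 and 0.44 for expressed families, and 0.065, 0.0031 and 0.11 for families not expressed, which were at 0.0063 in 3′ UTRs. The estrogen-induced median at 24 h was 0.52 without and 0.56 with protection at a pseudocount of 0.5, and 0.60 without protection on exonic peaks.

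Between primers, among such medians, exonic peaks alone turned the medians of cell cycle genes at 24 h (0.015), luminal genes at 0 h (0.096) and 6 h (0.12), abundant messenger RNAs at 24 h (0.16) and nuclear long noncoding RNAs at 24 h (0.49), and thinning turned that of the microRNA pathway at 6 h (0.056). Among the other medians, not counted, exonic peaks turned others between primers, including abundant messenger RNAs at 0 h (0.33), nuclear long noncoding RNAs at 0 h (0.66) and 6 h (0.46), and ribosomal protein genes at 24 h (0.20). Exonic peaks also turned the unprotected log2 ratio of ESR1 at 24 h (0.23).

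Leaving out each time pair in turn gave 14.5 to 18.9 points for TCAGTC, -0.104 to 0.0428 for GTGTCA, -11.7 to -9.28 for 3′ UTRs, -8.18 to -6.24 for coding sequence, -0.438 to -0.305 for 5′ UTRs, -0.577 to -0.469 for noncoding exons, 16.3 to 20.3 for introns, -0.171 to 0.546 elsewhere and 2.86 to 8.13 for sharing between primers. On the log2 scale it gave 0.13 to 0.56 for the ratio of peak numbers, 0.92 to 1.11 for let-7, 0.20 to 0.26 for expressed families and 0.02 to 0.05 for families not expressed. The lists hold no depth, so a gene with few peaks cannot be told from one sequenced little.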

Other observations

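The tests of separate cultures, of imperfect matches in stretches without the exact site, of exact primer 6-mers and list length for 3′ UTR shares, and of exonic peaks and thinned lists for estrogen-induced genes were chosen after the results were seen.

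Single genes not named above, some of them members of the lists, differed between primers or over time. Members of the known target list went both ways, with IGF1R, a growth factor receptor (chr15:99191768–99507759), at 54, 167 and 124 protected and 104, 301 and 391 unprotected peaks at 0, 6 and 24 h, of which 13, 35 and 39 protected and 7, 19 and 28 unprotected peaks were exonic. BTG2, an antiproliferative gene among the known microRNA targets (chr1:203274619–203278730), had 13, 12 and 12 protected peaks at 0, 6 and 24 h and 2, 4 and 1 unprotected peaks. TNRC6C, a GW182 protein that binds Argonaute (chr17:75954785–76104903), had 18, 21 and 39 against 4, 12 and 16, and its share without protection was 0.244, 0.435 and 0.249 times that with it. SLC26A2, a sulfate transporter (chr5:149340321–149373018), had 5, 39 and 39 protected peaks over estradiol time, a share 4.50 times as large at 24 h as at 0 h (1.77 to 14.6), and 3, 7 and 12 unprotected peaks. FLNB, an actin-binding filamin (chr3:57994125–58157978), had a share at 6 h 4.0 times that at 0 h with protection (1.69 to 11.5) and 3.08 times without (1.21 to 10.0).

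Unprotected 0 h peaks with TCAGTC recurred at 24 h in 57.3% of cases and those without it in 45.5%, against 29.3% and 28.8% of protected peaks. In 3′ UTRs, where control windows also lay in 3′ UTRs, let-7 sites were at 3.04, 2.33 and 2.44 times control at 0, 6 and 24 h with protection and at 1.19, 1.56 and 1.49 times without.

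The 10 genes with the largest excess of unprotected peaks, led by ERBB4, HMCN1 and LRFN5, had a median log2 ratio of 1.91 over protected peaks. TCAGTC was in 27.3% of the unprotected peaks of these genes and in 25.3% of all unprotected intronic peaks. Without peaks that hold it the median was 1.79, which argues against the exact 6-mer as the whole source. Leaving out so few peaks could not have removed the excess, so how much they contribute stays open. Imperfect matches were not examined for these genes. Per 10000 intronic peaks the median was 2.32, but this rise was not seen without the added pseudocount. Without the added pseudocount, the summed peaks of these genes had shares 6.33, 7.79 and 9.65 times those with protection at 0, 6 and 24 h, and 5.22, 6.17 and 7.03 times over intronic peaks. Mean intronic shares of 62.4% without and 43.7% with protection differed too little to give such ratios. A general intronic excess is thus argued against only as the whole source, and a part in the excess stays open. Separate cultures cannot be told apart from a primer effect, and the labels do not say whether RNA was shared. Genes with at least 20 peaks summed over the 6 lists numbered 5996. Of these, 17 were at least 4-fold higher without protection at all 3 times and 17 with it.

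The 3′ UTR share was 10.8 points lower without protection. Peaks at exact primer 6-mers were too few to be the whole source, with TCAGTC in 19.4% to 28.5% of unprotected peaks. Without them the difference was -9.97 points. Leaving them out could not have closed it wherever they lay, so how much they contribute stays open. Shorter or imperfect primer matches within 60 bases downstream are argued against only as the whole source, by -9.86 points without peaks that hold TCAG or a 1-mismatch TCAGTC there. These matches were in excess downstream of unprotected peaks by 22.7, 15.3 and 13.2 points over upstream stretches at 0, 6 and 24 h. So small an excess could not have closed the difference, so how much such matches contribute stays open. Such matches further downstream were not left out, and the excess of TCAGTC reached beyond 60 bases. At 0 h, unprotected peaks held 15.3 sites per 1000 in the bin that starts at 60 bases, against 2.56 in the outermost upstream bin. Longer unprotected lists as the whole source are argued against by -9.47 points at 0 h, where the unprotected list is the shorter. Among stretches without the exact site, such matches were in excess downstream of unprotected peaks over the flanks, by 11.8, 7.32 and 5.86 points, against 0.488, -0.0764 and 0.0592 points with protection. Imperfect matches more than 60 bases downstream, priming that needs still fewer paired bases, and different RNA behind the primers stay open. No biological explanation was tested.

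Estrogen-induced genes held larger shares of peaks at 24 h with both primers. The lower of both primers' percentiles was 99.825 without peaks that hold primer 6-mers and 100 on exonic peaks alone. Percentiles near 100 cannot show how much of a change was lost. Without peaks that hold primer 6-mers the medians were 0.31 without and 0.34 with protection, against 0.36 and 0.38 over all peaks. These values argue against mispriming at these 6-mers, and against intronic peaks, as the whole source. Longer lists at 24 h that reach weaker sites cannot be told apart from an effect of estradiol: the percentile was 99.995 with lists thinned to the shortest, but random thinning keeps the expected share of each gene, and no score ranks the peaks. Peak lists cannot separate more of these RNAs in the cell from more Argonaute on each RNA, and 1 library per time leaves differences between preparations open.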
